A study of Etheostoma caeruleum with 28 samples.

How the data were processed

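Gonad RNA of 28 fish was hybridised to one-colour Cy3 arrays, 4 arrays on each of 7 slides. Per the file headers, the arrays were extracted with Agilent Feature Extraction 10.7.1.1, and the deposited processed signal is an intensity that was background-subtracted within the array and not scaled between arrays. The deposited spot median and local background median are raw intensities, per the file headers. The value table that the authors deposited holds values that match a log2 scale with nearly equal quartiles on every array, close to quantile-normalized processed signal when set against the scanner values; its centring is not given in the sources used here, 8.55% of its cells were empty and 500 of 176026 non-control spots were absent. It served only as an alternative.

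Each array held 180880 spots, of which 176026 were not controls. The main values were log2 processed signals minus the array's 75th percentile over non-control spots, with outlier-flagged spots (0.012%) dropped and the spots of a probe averaged. Probes were kept if well above background on every array of at least 1 group (93051 probes). A further 135 without an unflagged spot on some array were left out, which gave 92916 tested. Slide, scan day and array position were read from the files and used as alternatives. The array 75th percentile ranged from 9.95 to 11.99 log2 units and the number of probes well above background from 80394 to 95191.

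All 6 groups entered 1 group-means model in limma 3.58.1 (R 4.3.3), with contrasts for 8 comparisons and Benjamini-Hochberg adjustment at 0.05 over all probes of a comparison. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The ovary and testis indices were compared with exact two-sided permutation tests. The index of an array is the summed difference from one reference mean divided by the summed difference between the reference means, over probes that differed at least 4-fold between reference ovary and reference testis. Neither compared group enters the reference means. All 6 groups enter the pooled spread and the background filter through which those probes were chosen. Array brightness relative to labelling controls used 7 of the 10 E1A spike-in probes, those well above background throughout.

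The model, comparisons, indices, other settings and naming rule were fixed before the data were examined. Not among the tests fixed then were the ovary index of severe against low intersex, the testis index of low intersex, and the tests of array level. The naming rule took, per comparison, called genes without overlap between the groups' arrays by size of change (overlap ignored for the difference of site effects). Since the files name no gene but alpha-tubulin, it was applied to 1 probe per contig and limited to 2 in each direction. For the same reason the 20 gene lists fixed beforehand matched 0 symbols and could not be tested. The other settings listed beforehand were quantile normalization, the authors' table, no filter, a stricter filter, slide or replicate number as a block, only the groups compared, array weights, a trended robust prior and leaving out each array. The files hold no mean signal column, so normexp (offset 50) used the spot median instead. That choice, scan day, array position and brightness terms, fits within a scan day, and the division of ovary arrays by scan day, and the tests of the closing section's unplanned patterns were chosen after seeing the data.

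The code was tested on simulated data drawn from the measured means and spreads of the 92916 probes, with 200 probes changed. For low intersex against exposed testis, 84% of 4-fold and 32% of 2-fold changes were recovered, with 14 false calls. For exposed ovary against reference ovary, these were 82%, 32% and 4. For exposed testis against reference testis, they were 88%, 39% and 7.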

Results

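Gonad transcripts were measured in the rainbow darter (Etheostoma caeruleum), a small freshwater fish, caught in one river either upstream of an urban area (reference site) or downstream of a municipal wastewater plant (exposed site). The 28 one-colour arrays comprised 5 reference testes, 5 exposed testes, 5 reference ovaries, 4 exposed ovaries, 6 gonads of severely intersex fish and 3 of fish with a low intersex index. Intersex gonads hold egg tissue within a testis. The labels placed both intersex groups at the exposed site and called the arrays of a group biological replicates. The low intersex fish carried an age label of 2 months, whereas the protocol described mature fish and the other groups were labelled adult. Of 109940 probes on the array, between 80394 and 95191 were well above background per array, and 92916 probes from 59072 sequence contigs were tested. Apart from an alpha-tubulin sequence with 2 probes, the files pair no probe with a gene name, so transcripts are given by probe. The number of arrays limits the precision of every value.

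Replicate arrays of a group correlated, across probes, at r of 0.975 to 0.989 in ovaries and non-intersex testes, and at 0.929 to 0.98 in severe intersex gonads. Probes are not independent replicates. Reference ovary and reference testis arrays correlated at 0.621 to 0.663. The first principal component held 82.4% of the variance and ordered the arrays from testis to ovary, with the 6 severe intersex gonads between them. The second component, with 4.98%, set the severe intersex gonads apart from all other arrays, and the third, with 2.99%, separated reference from exposed testes.

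The comparison of reference ovary with reference testis gave the scale on which the intersex gonads were read. Of the 92916 probes, 31927 were higher and 42376 lower in ovary. Probe GT_EA516_un_s_xh_8583 had a log2 difference of 14.82 ± 0.77 (SE, 5 against 5 arrays, limma adjusted p = 3.19e-15), although only 1 of the 5 testis arrays measured it well above background. Probe GT_EA516_an_as_sp_5984 was higher by 13.59 on the log2 scale, and 3 of 5 testis arrays measured it (14.2 without reference testis replicate 4). In the other direction, GT_EA516_un_s_xh_9378 and GT_EA516_un_as_xh_1931 were not well above background on any ovary array and were at least 8920-fold and at least 6250-fold higher in testis. These bounds set the mean of the brighter group against the lowest signal that counted as well above background on each array of the dimmer group, or the probe's own signal if that was higher. Set against the same limit, GT_EA516_un_s_xh_8583 and GT_EA516_an_as_sp_5984 were 9640-fold and 9340-fold higher in ovary. Differences of probes that only some arrays of the dimmer group measured rest partly on background, so their size and order are approximate. At a threshold of 4-fold, 11997 probes were ovary-enriched and 22049 testis-enriched. Of the calls, 43.0% were higher in ovary with scaling to the 75th percentile and 53.1% with quantile normalization, which moved the median log2 difference of all probes from -0.28 to 0.14.

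**Figure D1:**
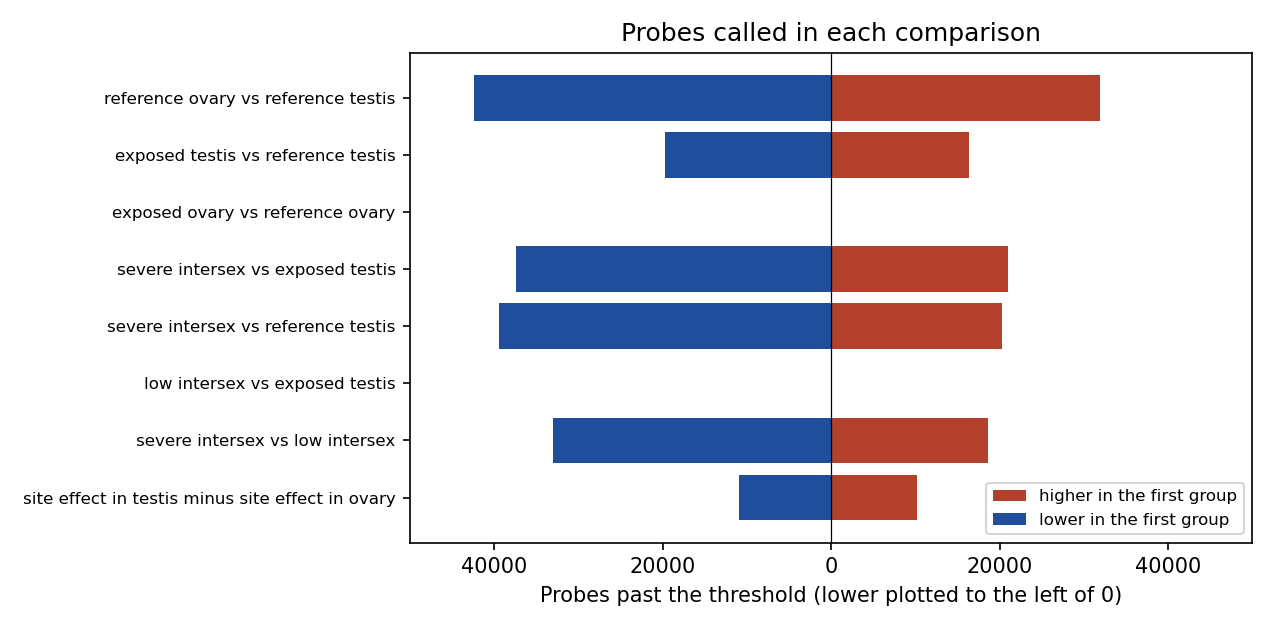
Number of probes past the threshold in each of the 8 comparisons, with probes higher in the first-named group drawn to the right of 0 and lower probes to the left. Exposed ovary against reference ovary (29 probes) and low intersex against exposed testis (9 probes) are too few to be visible on this axis.

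Severe intersex gonads were compared with exposed testes, which came from the same site. Ovary-enriched transcripts were higher as a group: 10172 of the 11997 ovary-enriched probes rose and 188 fell. Testis-enriched transcripts went the other way, with 15304 of 22049 (69.4%) lower and 224 higher. Probes enriched in neither sex also fell more often than they rose, with 21914 of 58870 (37.2%) lower and 10590 higher. Part of the fall was thus not particular to testis-enriched probes. Probe GT_EA516_un_s_xh_8583 rose by 12.14 ± 0.74 on the log2 scale (SE, 6 against 5 arrays, limma adjusted p = 6.82e-13), with 1 of 5 exposed testis arrays measuring it. Probe GT_EA516_un_as_xh_3633 was higher by 12.21, with 2 of the 5 measuring it, and set against the same limit the 2 probes were 1430-fold and 2810-fold higher. Probe GT_EA516_un_as_sp_10305 was not well above background on any severe intersex array and was at least 11.9-fold higher in exposed testis, and GT_EA516_un_s_sp_39248 had a log2 difference of -4.08, with 1 of 6 severe intersex arrays measuring it, and did not pass the threshold with array brightness as a covariate (-3.76). In all, 20986 probes were higher and 37406 lower in severe intersex gonads. With array brightness as a covariate the count was 14912, with 1229 testis-enriched probes lower and 6064 ovary-enriched probes higher. Of the calls, 35.9% were higher in the main setting, 54.6% with brightness as a covariate and 24.1% with normexp background correction.

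An ovary index placed each array between the mean reference testis (0) and the mean reference ovary (1) over the ovary-enriched probes. The severe intersex gonads had an ovary index of 0.604 ± 0.16 (SD, n = 6), and ranged from 0.418 to 0.783. The exposed testes had an index of 0.0404 ± 0.012 (SD, n = 5). The difference of 0.564 was larger than the spread between replicates (exact two-sided permutation test, p = 0.00433, the smallest the 462 splits can give, Benjamini-Hochberg adjusted p = 0.0108 over 5 index tests). A testis index, built in the same way from the testis-enriched probes, was 0.686 ± 0.13 (SD, n = 6) in severe intersex and 0.924 ± 0.021 (SD, n = 5) in exposed testis, a difference of -0.238 (exact permutation p = 0.00433, adjusted p = 0.0108).

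**Figure D2:**
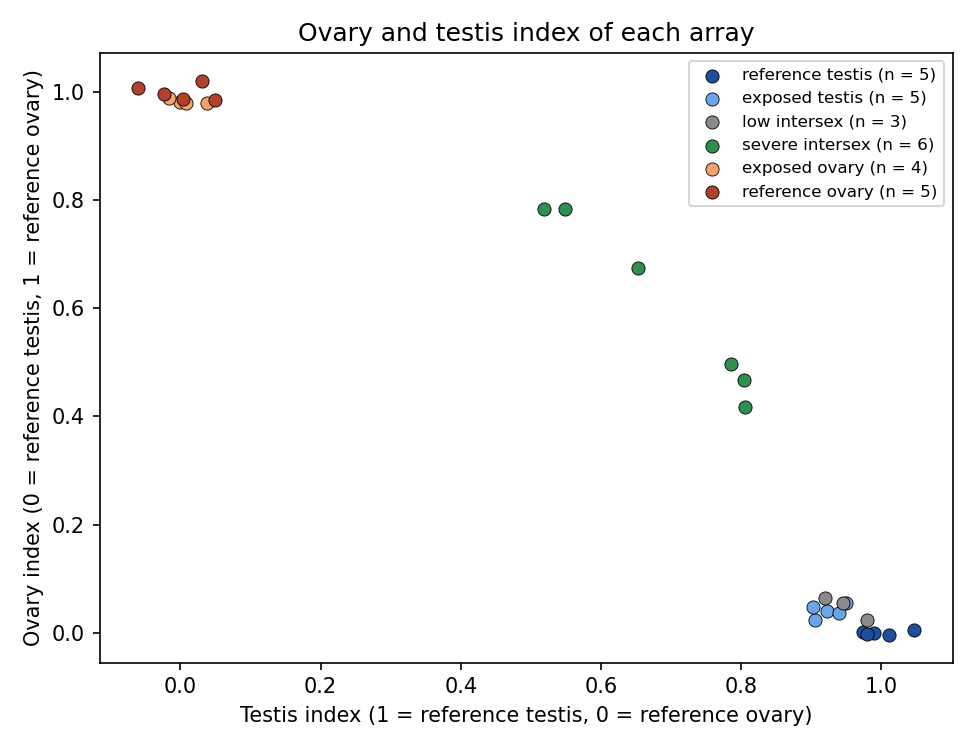
Ovary index against testis index for each of the 28 arrays, both without units, with 1 point per array and colour giving the group. The 6 severe intersex gonads lie between 0.418 and 0.783 on the ovary index, and the 3 low intersex gonads between 0.023 and 0.064.

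Against reference testis, the severe intersex gonads differed in both site and intersex state. In them 20219 probes were higher and 39443 lower. Probes GT_EA516_un_s_xh_8583 and GT_EA516_an_as_sp_5984 rose by 12.82 and 12.13 on the log2 scale, and 1 and 3 of the 5 reference testis arrays measured them (12.7 for the second without reference testis replicate 4). Probes GT_EA516_un_s_xh_3711 and GT_EA516_un_s_sp_6757 had log2 differences of -4.65 and -4.50, with 3 and 2 of 6 severe intersex arrays measuring them. With array position as a block the count fell to 36697 probes.

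Low intersex gonads were compared with exposed testes of the same site. Their ovary index of 0.0473 ± 0.022 (SD, n = 3) differed from that of exposed testes by 0.00694, less than the spread between replicates (exact two-sided permutation p = 0.536, 56 splits). Their testis index was 0.948 ± 0.031 (SD, n = 3) against 0.924 in exposed testis (exact permutation p = 0.25, adjusted p = 0.312), a test that was not planned. Of the 92916 probes, 7 were higher and 2 lower by limma, while 6327 had an unadjusted p under 0.05. Probe GT_EA516_un_as_sp_20366 was higher by 2.59 ± 0.38 on the log2 scale (SE, 3 against 5 arrays, limma adjusted p = 0.0151) and GT_EA516_un_as_sp_16066 by 1.45. Probes GT_EA516_un_s_sp_31630 and GT_EA516_un_s_sp_24615 had log2 differences of -1.29 and -1.16. Of 13 other settings, these 4 probes were not called in 4, 5, 7 and 7. The first was not called without low intersex replicate 1 or 2 or exposed testis replicate 4 (3.21 without low intersex replicate 3), and the others were called only without exposed testis replicate 2 or 3, without low intersex replicate 3 or exposed testis replicate 2, and without low intersex replicate 3 or exposed testis replicate 2 or 5. No probe was called with slide or scan day as a block, and 241 were called with array weights. The log2 differences of the 4 probes, in the order given, were 2.24, 1.36, -1.04 and -1.01 with slide as a block, and 2.42, 1.38, -1.14 and -1.13 with scan day.

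**Figure D3:**
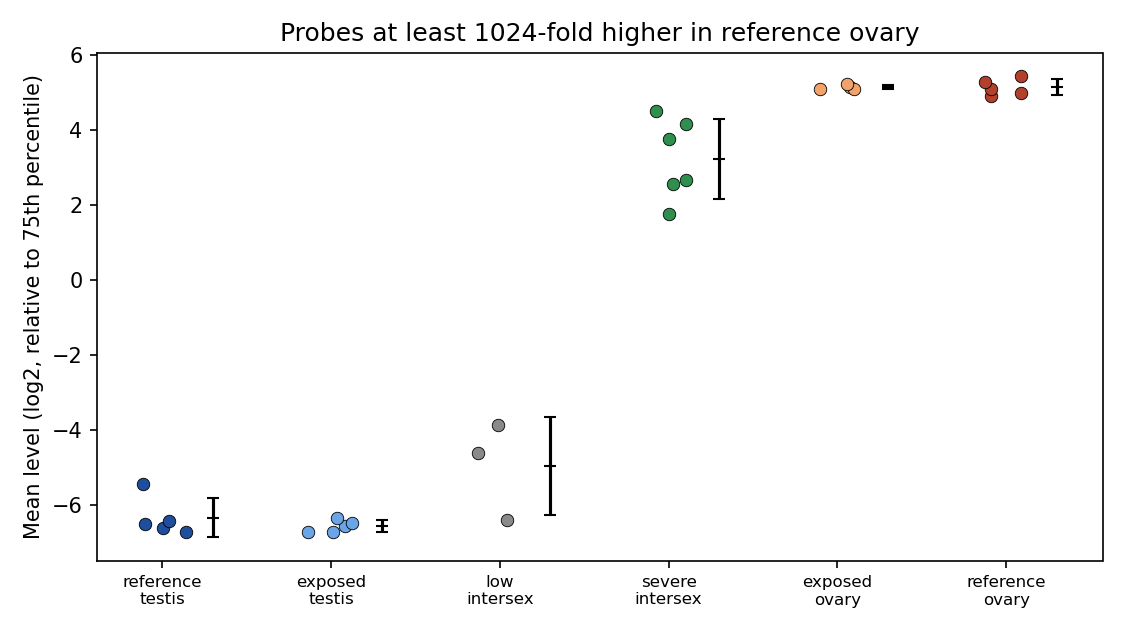
Mean log2 level, relative to the array's 75th percentile, of the 278 probes at least 1024-fold higher in reference ovary than in reference testis, with 1 point per array and the mean ± SD to the right. Low intersex replicates 1 and 2 lie at -3.88 and -4.63, above the exposed testis arrays.

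Severe intersex gonads differed from low intersex gonads in 18563 higher and 32989 lower probes. Of the ovary-enriched probes, 10038 were higher and 22 lower, and of the testis-enriched probes 15126 were lower and 92 higher. Of the 58870 probes enriched in neither sex, 17841 were lower and 8433 higher. Probe GT_EA516_un_s_xh_5914 rose by 10.28 ± 0.37 on the log2 scale (SE, 6 against 3 arrays, limma adjusted p = 9.69e-16). Probe GT_EA516_un_s_sp_1374 was not well above background on any low intersex array and was at least 258-fold higher in severe intersex. Probes GT_EA516_an_s_sp_1906 and GT_EA516_un_s_sp_31149 had log2 differences of -4.81 and -4.22, the second with -4.82 without severe intersex replicate 2 and no call with brightness as a covariate (-3.46). The ovary index was higher by 0.557 (exact permutation p = 0.0238, the smallest that 84 splits can give, adjusted p = 0.0397, a test that was not planned). Age label and intersex index differed together in this comparison. The count was 34316 with only these groups in the fit.

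The effect of the exposed site was examined separately in each sex. In testis, 16311 probes were higher and 19799 lower at the exposed site, and 14318 of these differed by at least 2-fold. Probe GT_EA516_un_s_sp_22914 was not well above background on any reference testis array and was at least 14.1-fold higher in exposed testis. Probe GT_EA516_un_s_sp_30922 was higher by 4.08 ± 0.61 on the log2 scale (SE, 5 against 5 arrays, limma adjusted p = 1.62e-05), with 2 of 5 reference arrays measuring it. Probe GT_EA516_un_s_sp_18745 was not well above background on any exposed testis array and was at least 8.15-fold higher in reference testis, and GT_EA516_un_s_sp_46469 had a log2 difference of -3.96 (-3.15 without reference testis replicate 1), with 1 of 5 exposed arrays measuring it. With brightness as a covariate GT_EA516_un_s_sp_30922, GT_EA516_un_s_sp_46469 and GT_EA516_un_s_sp_18745 did not pass the threshold (2.84, -3.06 and -2.89), nor did GT_EA516_un_s_sp_22914 with array position as a block (3.04). The alpha-tubulin sequence on the array, a subunit of microtubules, was higher in exposed testis on both of its probes, by 1.08 and 0.88 on the log2 scale (limma adjusted p = 0.000597 and 1.08e-05). With brightness as a covariate neither alpha-tubulin probe passed it, at 0.43 and 0.51 (adjusted p = 0.405 and 0.0647).

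The exposed testis arrays were also dimmer, with a mean 75th percentile of 10.09 log2 units against 11.22 in reference testis. The spike-in probes were brighter on the exposed testis arrays, at a mean of 13.14 against 12.24. Both parts enter the level of the exposed testis arrays relative to the spike-ins. Their 75th percentile relative to the E1A spike-in probes, added in fixed amount during labelling, was -3.06 ± 0.18 log2 units (SD, n = 5) against -1.02 ± 0.13 (SD, n = 5) in reference testis (exact permutation p = 0.00794, the smallest the 252 splits can give, adjusted p = 0.0185 over 7 array tests). All 5 exposed testis arrays were scanned on the second of 2 scan days, and all 5 reference testis arrays sat at the first position of their slide. The count of 36110 probes was 22381 within the second scan day, 31493 with scan day as a block, 28846 with slide as a block, 18553 with array position as a block and 15022 with brightness as a covariate. On the first scan day there were no exposed testis arrays. The share of calls that were higher was 45.2%, but 69.3% with normexp background correction, which moved the median log2 difference of all probes from -0.07 to 0.24.

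**Figure D4:**
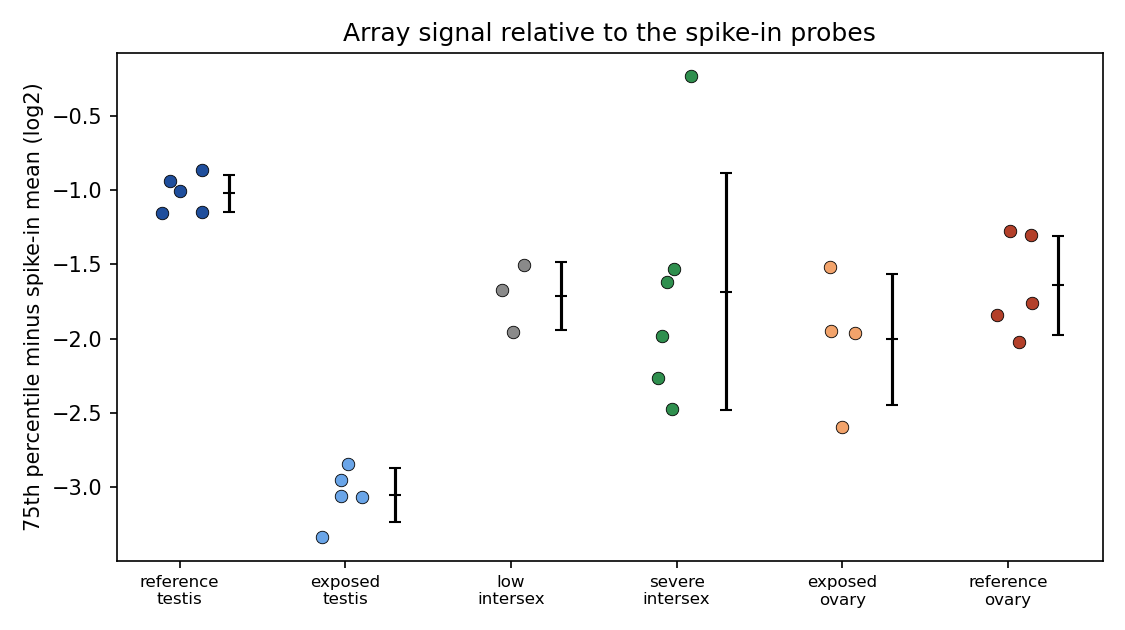
The 75th percentile of each array minus the mean of its spike-in probes (log2) by group, with 1 point per array and the mean ± SD drawn to the right. The 5 exposed testis arrays lie at a mean of -3.06, below all arrays of the reference testis group, whose mean was -1.02.

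In ovary, 10 probes were higher and 19 lower at the exposed site, and 5036 had an unadjusted p under 0.05 by limma. Probe GT_EA516_un_s_xh_1057 was higher by 7.68 ± 0.81 on the log2 scale (SE, 4 against 5 arrays, limma adjusted p = 6.99e-05), with 3 of 5 reference ovary arrays measuring it, and GT_EA516_un_s_xh_347 was higher by 5.63. Probe GT_EA516_an_as_sp_2256 was not well above background on any exposed ovary array and was at least 13.8-fold higher in reference ovary, and GT_EA516_un_s_sp_30519 had a log2 difference of -5.12, with 1 of 4 exposed arrays measuring it. These 2 lower probes were not called in 6 and 7 of 12 other settings. When 1 of the 9 arrays was left out, the first was called only without reference ovary replicate 5 (-5.65), and the second only without reference ovary replicate 1 or exposed ovary replicate 2. With only the ovary groups in the fit 2 probes were called, all higher, and with array weights 78 (26 higher and 52 lower). The balance of directions depended on single arrays, with 10 higher and 2 lower without exposed ovary replicate 1, and 7 and 19 without exposed ovary replicate 4.

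The site effects in testis and ovary were then compared directly. They differed between the sexes in 21049 probes, with 10136 more positive and 10913 more negative in testis. The array level relative to the spike-in probes also differed by site in testis (-2.03 log2 units, exact permutation adjusted p = 0.0185), and less in ovary (-0.365, adjusted p = 0.24). A sex-dependent site effect therefore cannot be told apart from the difference in array level. Probe GT_EA516_un_s_sp_45734 had a difference of 7.02 ± 1.81 on the log2 scale (SE, limma adjusted p = 0.00701) and GT_EA516_un_s_sp_23820 one of 6.10. Only 1 of 4 exposed ovary arrays measured the first, and 2 of 4 exposed ovary, 2 of 5 reference testis and 4 of 5 exposed testis arrays the second. Leaving out 1 array gave 5.97 (reference testis replicate 3) to 8.73 (exposed ovary replicate 1) for the first and 5.15 (exposed ovary replicate 3) to 7.02 (exposed testis replicate 5) for the second. Neither passed the threshold with brightness as a covariate, although their differences were no smaller (7.18 and 6.3), nor did the second with array position as a block (4.19). Probes GT_EA516_un_s_xh_1057 and GT_EA516_un_s_xh_347, both higher in exposed ovary, had differences of -8.43 and -5.91. The count was 7065 within the second scan day, 13477 with slide as a block, 11685 with array position as a block and 9444 with brightness as a covariate. Of the calls, 48.2% were more positive in testis, against 66.6% with normexp background correction.

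Each slide held 4 arrays of several groups, and the arrays were scanned on 2 days. Within the first and second scan day, 61970 and 67474 probes differed between reference ovary and reference testis, 5 and 37 between exposed and reference ovary, and 48906 and 36691 between severe intersex and reference testis. Severe intersex differed from exposed testis in 44654 probes on the second day, and from low intersex in 43033 on the first. On the second day, 22381 probes differed between exposed and reference testis and 7065 in the site effects. The day comparisons not given here had at most 1 array in a group. On single slides that held both groups of a comparison, 94.4% to 100% of the called probes differed in the called direction, over arrays that also entered the calls.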

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

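The tests of scan day in testis, of dividing the ovary arrays by scan day, of RNA amount, of a leak between neighbouring arrays and of single arrays were chosen after the results were seen, whereas those of array position, brightness, additive mixtures, scaling, 3-array sets and other splits were written down before their own results. By then the fits with scan day or position as a block and brightness as a covariate, and the size of the set above both tissues, had been seen. The 1024-fold limit for ovary-specific probes was also set after the data were seen.

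The site effect differed between testis and ovary in 21049 probes by a direct test of the difference. The array level relative to the spike-ins differed by site mainly in testis, so a sex-dependent site effect cannot be told apart from it. Site was shuffled within each sex in 100 splits, and 2 of these, the real one included, gave as many probes. The highest other split gave 23213 and had every exposed testis array exchanged with a reference testis array, so it kept the testis groups whole. The next highest gave 20870.

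The first pattern is the large difference between exposed and reference testis (36110 probes against at most 66 in the other splits, 1 of 100 as large). Scan day would leave exposed-site fish of the first day at the reference end of the axis that runs from reference testis (0) to exposed testis (1), but the 2 low intersex arrays of that day lay at 0.612 and 0.736 relative to reference testes of the same day, on an axis made from second-day arrays. The exposed-site testis arrays at the first slide position lay at 0.865 (low intersex replicate 3) and 0.874 (exposed testis replicate 5), which argues against position as the whole cause. The trend with brightness inside groups, over 22 arrays, gave a share of 0.071 ± 0.101 (jackknife SE) of the difference. The severe intersex arrays were left out of it. The array 75th percentiles did not overlap between exposed (9.95 to 10.39) and reference testis (11.1 to 11.35). The trend was thus extended beyond the spread within groups and cannot bound the part of brightness, which stays open. With brightness as a covariate, in a fit of all 6 groups, 15022 probes were called. Over the 25019 no longer called, the median size of change went from 0.846 to 0.522 log2 units. Their median SE went from 0.221 to 0.345. The trend with the level relative to the spike-ins, over 22 arrays and extended in the same way, gave a share of 0.228 ± 0.137 (jackknife SE). The 3 low intersex arrays lay 0.309 to 0.545 nearer to exposed testis than that level would place them (other testis arrays -0.267 to 0.19). Their level was 1.34 log2 units above that of exposed testis (exact permutation p = 0.0357, adjusted p = 0.05 over 7 array tests). Yet only 9 probes were called between these groups. For the low intersex arrays, these values argue against that level as the whole cause. But the share plus 2 SE reached 0.501. The amount of RNA therefore stays open at least in part, as do its quality and the capture site, which were not tested separately.

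The second pattern is a set of 477 probes that were higher in severe intersex than in both exposed testis and exposed ovary by at least 2-fold, with 117 lower than both, whereas at any fold 1116 were higher and 4202 lower. An additive mixture of testis and ovary RNA cannot exceed its richer part, and 20 simulated mixtures gave at most 1 such probe, while 157 of the 477 were higher on every severe intersex array than on any array of either tissue. The simulated parts were the mean exposed testis and the mean exposed ovary, so the simulation speaks only to mixtures of those means. Exposed testis arrays had a lower level relative to the spike-ins (mean -3.06, against -1.68 in severe intersex). The set was not read with brightness as a covariate or against reference testis, so a mixture is not excluded in general. Scaling does not account for most of the set, since 58.5% were still above both under quantile normalization, but normexp background correction gave only 145. Cell types or stages that neither whole tissue holds, and the measured intersex state itself, may contribute and were not tested.

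The third pattern is the small number of calls (9) between low intersex and exposed testis. Small group size does not explain the contrast with severe intersex, since the 20 sets of 3 severe intersex arrays called at least 42160 probes against exposed testis. Among the 56 splits of these 8 arrays, 3 gave as many calls, with up to 84 where exposed testis replicates 1, 3 and 5 were set against the rest, which points to a structure among these arrays, so chance cannot be excluded for the 9 probes. Yet the 278 probes at least 1024-fold higher in reference ovary had mean levels of -3.88 and -4.63 in low intersex replicates 1 and 2, against -6.41 in replicate 3, -5.44 in reference testis replicate 4, which has no ovary or severe intersex array beside it, and -6.74 to -6.36 on the 9 other testis arrays, which do and on which 86 to 171 of the 278 were well above background (246 and 215 in low intersex replicates 1 and 2, and 215 in reference testis replicate 4). Low intersex replicates 1 and 2 had an ovary or severe intersex array beside them, and replicate 3 did not. Reference testis replicates 1 and 2, on the same slides as those 2 and also with such a neighbour, lay at -6.52 and -6.74. A leak at every such neighbour would have raised the 9 other testis arrays, while a leak on single slides, carry-over at dissection, or a small amount of egg tissue may each remain.

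In the comparisons between unlike gonads, the real grouping called more probes than any other split run. For reference ovary against reference testis it called 74303 probes against at most 55113 elsewhere (1 of 100 splits). For severe intersex the counts were 58392 against 38892 with exposed testis (1 of 100) and 59662 against 40808 with reference testis (1 of 100). With low intersex they were 51552 against 50141 (1 of 84). Those counts speak against chance without excluding it, and least for severe against low intersex, where another split came close. Chance also stays open for exposed against reference ovary over both days, where 5 of 100 splits gave as many as the 29 probes and the highest gave 299. That split called several times the real count, and its group of 4 held only arrays of the second scan day, as did those of the next 2 splits (170 and 91 probes). Dividing the 9 ovary arrays by scan day alone, a split not among those drawn, gave 1931 probes, so the ovary arrays were structured along scan day, or the slides that went with it, more than along site. With scan day as a block the site comparison gave 30 probes. Among the 60 splits within scan days only the real one (1 of 60) gave as many, with 25 in the highest other. That speaks against chance with this block only, since the comparison gave 9 probes with slide and 4 with array position as a block. Within the first and second day alone the site comparison gave 5 and 37.

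A control feature outside the main measurement, with 40 spots per array, had a log2 processed signal of 11.9 ± 0.17 (SD, n = 5) in exposed testis and 12.1 ± 0.323 (SD, n = 3) in low intersex, against 10.8 ± 0.589 (SD, n = 5) in reference testis, 4.19 ± 0.534 (SD, n = 5) in reference ovary, 3.92 ± 0.976 (SD, n = 4) in exposed ovary and 9.15 ± 1.52 (SD, n = 6) in severe intersex. These signals were not scaled between arrays. Mean array 75th percentiles were 10.09 in exposed testis, 10.66 in low intersex and 11.22 in reference testis, so the size and order of differences among these groups depend on scaling.

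Single arrays stood apart from their group in 17 of 155 groups of values examined, where chance gives about 1 in 20. In exposed ovary these were replicate 2 for GT_EA516_un_s_xh_8583 (5.94) and GT_EA516_un_as_sp_20366 (-2.99), replicate 3 for GT_EA516_un_s_xh_9378 (-8.63) and replicate 1 for GT_EA516_un_s_sp_45734 (-2.19). In reference ovary they were replicate 1 for GT_EA516_un_as_xh_1931 (-7.12), GT_EA516_un_as_sp_10305 (-7.46) and GT_EA516_un_as_sp_16066 (-1.74), replicate 2 for GT_EA516_un_s_xh_1057 (-5.09), and replicate 3 for GT_EA516_un_s_xh_3711 (-7.43) and GT_EA516_un_s_sp_6757 (-8.55). In testis they were reference replicate 1 for GT_EA516_un_s_sp_46469 (0.48), reference replicate 4 for GT_EA516_un_s_sp_31149 (1.47), exposed replicate 1 for GT_EA516_un_s_xh_1057 (-3.40) and GT_EA516_un_s_xh_347 (-2.05), and exposed replicate 5 for GT_EA516_un_s_sp_24615 (-3.16) and GT_EA516_un_s_sp_23820 (-7.20). In severe intersex, replicate 6 stood apart for GT_EA516_un_as_sp_20366 (-1.22). No reference ovary array measured GT_EA516_un_as_xh_1931 or GT_EA516_un_as_sp_10305 well above background. The same held for GT_EA516_un_s_xh_9378 on the exposed ovary arrays. For these probes the array that stood apart differed only at background.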

How the results depend on the processing

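The scan day, array position, brightness and normexp settings, and all settings for probes above both tissues, were chosen after seeing the data. The cause was not tested for any change given here. Quantile normalization and the trended prior moved no count of probes by over 1.5 times, and the series table moved only exposed against reference ovary (15 probes against 29). Exposed ovary gave 5 on the first scan day, 11 with normexp, 19 with no filter, 10 with the stricter filter, 9 with slide and 4 with position as a block, 2 with only its groups and 78 with array weights. Low intersex against exposed testis (9) gave 4 with normexp, 0 with slide or scan day as a block (3819 and 4413 at an unadjusted p under 0.05), 18 with position, 2 with brightness, 4 with only its groups and 241 with array weights. Exposed against reference testis (36110) gave 18553 with position, 15022 with brightness and 22381 on the second scan day; severe intersex gave 36697 with position and 36691 on the second scan day against reference testis, 14912 against exposed testis with brightness and 34316 against low intersex with only its groups. The difference of site effects gave 13477 with slide, 11685 with position, 9444 with brightness and 7065 on the second scan day. Of the enriched sets in severe intersex against exposed testis, brightness as a covariate gave 1229 against 15304 testis-enriched probes lower and 6064 against 10172 ovary-enriched probes higher. Over the 58392 probes of that comparison called without brightness, the median size of change went from 1.02 to 0.66 log2 units and the median SE from 0.227 to 0.347. Over the 44525 no longer called, these went from 0.938 to 0.529 and from 0.229 to 0.348. The other comparison counts under these settings stayed within 1.5 times of the main one.

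Leaving out 1 array gave 12 to 35 probes for exposed ovary (12 without exposed ovary replicate 1 or 3, 19 without exposed replicate 2, 16 without reference replicate 5). For low intersex it gave 0 to 201 (0, 1 and 201 without low intersex replicates 1, 2 and 3, 121 and 1 without exposed testis replicates 2 and 4). Against exposed testis, the severe intersex indices kept their direction and their side of the threshold in every setting run, at 0.482 to 0.629 (ovary) and -0.29 to -0.205 (testis). These settings were quantile normalization, limits of 2-fold and 8-fold, normexp and leaving out 1 array. Brightness, scan day, slide and position were not run for the indices, although the mean array 75th percentile was 11.14 in severe intersex and 10.09 in exposed testis. No other setting was run for the index of severe against low intersex or for the testis index of low intersex. The low intersex ovary index difference was -0.00277 with quantile normalization, -0.000727 at 2-fold, 0.0166 at 8-fold, -0.0358 with normexp and -0.00148 to 0.0192 without 1 array, where the splits are too few for a p under 0.05. It did not pass the threshold in the other settings. Of the values for single probes, enriched sets and probes above both tissues, 3 moved by over 1.5 times (the 2 enriched sets with brightness, and 145 against 477 probes above both with normexp), 808 kept direction and call or stayed within 1.5 times, 82 kept direction only (43 for low intersex against exposed testis and 28 for exposed ovary), and none reversed.

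Replicate numbers did not pair the arrays: with each probe's group mean removed, same-numbered arrays correlated at -0.14 to 0.19, and in no comparison did all arrays correlate best with their own number. With the replicate block, low intersex gave 4 probes, and the other counts stayed within 1.5 times. The gene list alternatives were not run, because no list could be matched, nor was normexp on the mean signal. Probes near background limit the smallest levels.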

Other observations

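All tests in this part were chosen after the results were seen.

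The severe intersex gonads differed among themselves in how much ovary signal they carried. When each array was described as a sum of the mean exposed testis and the mean exposed ovary, the ovary part was 78.0% in replicate 1, 73.0% in replicate 3, 49.7% in replicate 5, 24.9% in replicate 4, 23.5% in replicate 2 and 19.3% in replicate 6. Their 278 most ovary-specific probes had mean levels between 1.74 and 4.49 log2 units relative to the array's 75th percentile, against 4.89 to 5.43 in reference ovary. One reference testis, replicate 4, also stood higher than the other reference testes on these probes, at -5.44, and had no ovary or severe intersex array beside it. Over the 757 probes at least 256-fold higher in reference ovary, low intersex replicates 1, 2 and 3 stood at -4.41, -4.93 and -5.65, against -5.90 to -5.65 in exposed testis and -5.24 in reference testis replicate 4. Over the 1563 probes at least 64-fold higher they stood at -4.52, -4.84 and -5.13, against -5.33 to -5.14 in exposed testis, so the distance shrank as the limit was lowered.

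Low intersex gonads, caught at the exposed site, differed from reference testis in 9457 higher and 12420 lower probes, a comparison that was not planned.

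A candidate explanation for part of the exposed testis profile is a small shift towards the ovary profile. The index was rebuilt from the 2 reference testes of the second scan day, over probes well above background on every testis array, and read in the 3 reference testes left out of it. The exposed testes were higher by 0.0518 (exact permutation p = 0.0357, the smallest that 56 splits can give), by 0.0766 with quantile normalization and by 0.0798 with normexp background correction. These exposed and reference testes were scanned on different days. Within the second day, on an axis made from the 3 first-day reference testes, the exposed testes were higher than the 2 reference testes by 0.0615 ± 0.00577 (SE, 5 against 2 arrays), and by 0.0755 ± 0.00886 (SE) with quantile normalization, which argues against scan day as the cause, although 21 splits are too few for a p under 0.05. Levels relative to the spike-ins did not overlap between exposed and reference testes, so site and RNA amount cannot be told apart in this test.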
